A study of Mus musculus with 46 samples.

How the data were processed

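RNA sequencing of P14 CD8 T cells, sorted from mouse splenic red pulp and white pulp on days 0, 7, 11, 15 and 33 of LCMV Armstrong infection, was analysed from 1 deposited table of 24127 gene symbols by 46 libraries. Per the labels, RNA was purified with a QIAGEN RNeasy Micro kit, amplified with Clontech SMARTer chemistry and sequenced as single 100-base reads on an Illumina HiSeq 1000 after Nextera XT library preparation. The labels name TopHat, Cufflinks, DESeq2 and DESeq with the builds GRCm38 and mm10, while versions, the counting tool, the annotation release and any filter are not given in the sources used here. The deposited values are signal values, read counts divided by the authors by 1 size factor per library: in every column 100% of the values were whole multiples of the smallest value above 0 (tolerance 0.001). Multiplying by that factor recovered the reads, 2534073 to 9952522 per library (median 5776799), against deposited totals of 4857075 to 5888460. Symbols were placed on the genome with GENCODE M21 (GRCm38), which held 22947 of them (95.11%).

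Libraries formed 10 groups by compartment and day, with 5 libraries each, except 4 on day 7 in both compartments (no replicate 2) and 3 in red pulp on day 33 (replicates 3, 4 and 5). The series description says that libraries 41 and 42 were removed for poor quality. The labels call the numbered libraries of a group biological replicates, and they do not say whether the same number in both compartments means the same mouse, so libraries were treated as independent. Correlations between replicates ran from 0.631 (median 0.9396), and the lowest belonged to white pulp day 11 replicate 1, which was kept.

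Genes with a mean of at least 10 normalized counts over all libraries were tested (11219, 46.5% of the table). Values were taken as log2(value + 1) and fitted in R 4.3.3 with limma 3.58.1 (trend), with 1 mean per group over all 46 libraries, and genes were called at a Benjamini-Hochberg adjusted p below 0.05. The 17 comparisons were white against red pulp on each day and for the mean of days 7 to 33, each later day against day 0 and day 33 against day 7 in each compartment, and an F test of the compartment by day interaction. Log2 fold changes are white less red pulp or the later less the earlier day, SE is the standard error of the fit, and SD is between libraries.

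The 26 gene lists, fixed before the data were examined, were naive and memory precursor, terminal effector, cytotoxic and cytokine, trafficking receptor, tissue residency (higher and lower), cell cycle, T cell receptor response, dissociation and heat shock, type I interferon response, inhibitory receptor and exhaustion, cytokine receptor, T cell transcription factor, glycolysis, oxidative phosphorylation, fatty acid oxidation and cholesterol synthesis genes, and markers of B cells, macrophages or monocytes, neutrophils, erythroid cells, platelets, dendritic cells, NK cells, CD4 T cells and stromal or endothelial cells. They were tested with camera at a preset correlation of 0.01, with adjustment over the 26 lists of a comparison, and again with a correlation estimated from the data and with fry. Genes were named by a rule written beforehand: the 6 largest rises and the 6 largest falls of each comparison among genes called with an absolute log2 fold change of at least 1, a mean of at least 50 in the higher group and no overlap between the groups' libraries (not required for the mean of days), leaving out symbols starting with Gm or mt- or ending in Rik or Ps. To these came up to 4 called members of each list with the smallest adjusted p, and always genes fixed beforehand, among them Ccr7, S1pr1, Klf2, Il7r, Tcf7, Klrg1, Cx3cr1, Tbx21, Eomes, Zeb2, Gzma, Gzmb, Cxcr3, Itgae, Cd69, Mki67, Cd8a and Cd3e. The text leaves out many genes this rule gives for length, and those with a group wholly at 0, those in the missing chromosome stretches for white pulp day 11, and a few that share reads with close paralogs. Results of a few further genes are not reported here.

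Alternatives chosen before the data were examined were a pseudocount of 5, a mean of at least 1, TMM rescaling, library quality weights, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, a block on replicate number, a fit to the groups compared alone, and leaving out each library in turn. After the data were seen, the missing stretches set aside and the mean log2 values of the macrophage and B cell lists as covariates were added. Counts of 11219 genes were simulated with known changes, but not between compartments on day 0. On day 7 limma recovered 70.1, 91 and 97% of genes changed 2, 4 and 8-fold, with 5.49% false calls. On day 33 the shares were 62.7, 86.6 and 98.5% (4.62% false), for the mean of days 94, 98.5 and 100% (6.25%), and for day 33 against day 7 in red pulp 44.8, 79.1 and 95.5% (2.01%). DESeq2 made 10.7% false calls on day 7. Real rates may differ.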

Results

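P14 CD8 T cells, which carry a T cell receptor specific for lymphocytic choriomeningitis virus (LCMV), were compared between splenic red pulp and white pulp on day 0 and on days 7, 11, 15 and 33 of LCMV Armstrong infection. The 46 libraries held 2534073 to 9952522 reads (median 5776799) and 10908 to 13482 genes above 0. Groups held 5 libraries (4 on day 7, 3 in red pulp on day 33). Each day had its own, so day and handling cannot be parted. On every later day, in both compartments, 20 to 23 of 27 naive and memory precursor genes were called below day 0 and 14 to 18 of 21 cytotoxic and cytokine genes above it, and cell cycle genes were highest on day 7. Compartments differed mainly on days 0 and 15 (1414 and 87 genes, fitted alone 383 and 396), and most genes were lower in white pulp.

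Markers of other spleen cells were present in the sorted P14 libraries at levels that differed by compartment and by day. The mean log2 level of 20 macrophage and monocyte markers was 10.44 ± 0.34 (mean ± SD, n = 5) in red pulp and 5.88 ± 0.94 (n = 5) in white pulp on day 0. In red pulp it was 7.58 ± 0.75 on day 7 (n = 4), 6.20 ± 0.50 on day 11 (n = 5), 9.85 ± 0.34 on day 15 (n = 5) and 6.03 ± 1.84 on day 33 (n = 3, with replicate 5 at 8.13 and the others at 4.66 and 5.30). White pulp gave 4.34 ± 0.34 (n = 4), 4.45 ± 0.57 (n = 5), 7.44 ± 0.51 (n = 5) and 4.87 ± 1.04 (n = 5) on the same days. C1qb, a chain of complement component C1q made by macrophages, stood at 3151 ± 832 normalized counts in red pulp and 143 ± 93.9 in white pulp on day 0, and at 1705 ± 403 and 258 ± 98.2 on day 15. The mean log2 level of 15 B cell markers was 10.33 ± 0.14 in red and 9.17 ± 0.39 in white pulp on day 0 and 7.09 ± 0.27 and 7.06 ± 0.44 on day 7. On day 0, 0 of 20 macrophage and monocyte markers were higher and 19 lower (0 and 20 adjusted over the list alone, median log2 fold change -4.56, camera adjusted p = 1.7e-31, adjusted p = 0.00314 with an estimated correlation) in white relative to red pulp. Of the other cell types, 0 of 15 B cell markers were higher and 8 lower (0 and 14 adjusted over the list alone, median log2 fold change -1.11, camera adjusted p = 9.7e-06, adjusted p = 0.356 with an estimated correlation). Further, 0 of 10 neutrophil markers were higher and 2 lower (0 and 5 adjusted over the list alone, median log2 fold change -1.81, camera adjusted p = 0.0457, adjusted p = 0.559 with an estimated correlation). Among erythroid markers, 0 of 12 genes were higher and 1 lower (0 and 5 adjusted over the list alone, median log2 fold change -2.72, camera adjusted p = 0.0153, adjusted p = 0.423 with an estimated correlation). Among platelet markers, 0 of 2 genes were higher and 0 lower (0 and 0 adjusted over the list alone, median log2 fold change -0.14, camera adjusted p = 0.751, adjusted p = 0.806 with an estimated correlation), the test's direction being up. For dendritic cells, 0 of 8 markers were higher and 2 lower (0 and 3 adjusted over the list alone, median log2 fold change -1.78, camera adjusted p = 0.00936, adjusted p = 0.0453 with an estimated correlation). For NK cells, 0 of 8 markers were higher and 6 lower (0 and 7 adjusted over the list alone, median log2 fold change -2.35, camera adjusted p = 4.4e-07, adjusted p = 1.5e-04 with an estimated correlation). For CD4 T cells, 0 of 9 markers were higher and 1 lower (0 and 1 adjusted over the list alone, median log2 fold change -0.20, camera adjusted p = 0.617, adjusted p = 0.806 with an estimated correlation). For stromal and endothelial cells, 0 of 2 markers were higher and 1 lower (0 and 1 adjusted over the list alone, median log2 fold change -3.21, camera adjusted p = 0.0456, adjusted p = 0.0907 with an estimated correlation). Neutrophil markers lost the camera call in 6 of 10 fits with 1 library left out (adjusted p up to 0.257 without red pulp day 0 replicate 3). Erythroid markers lost it in 1 of 10 fits (0.0576 without red pulp day 0 replicate 3). Stromal and endothelial markers lost it in 6 of 10 fits (up to 0.0831 without white pulp day 0 replicate 5). The NK cell list shares Gzma, and the dendritic cell list Itgax, with the lists of effector genes or trafficking receptors, and activated CD8 T cells express both.

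**Figure D1:**
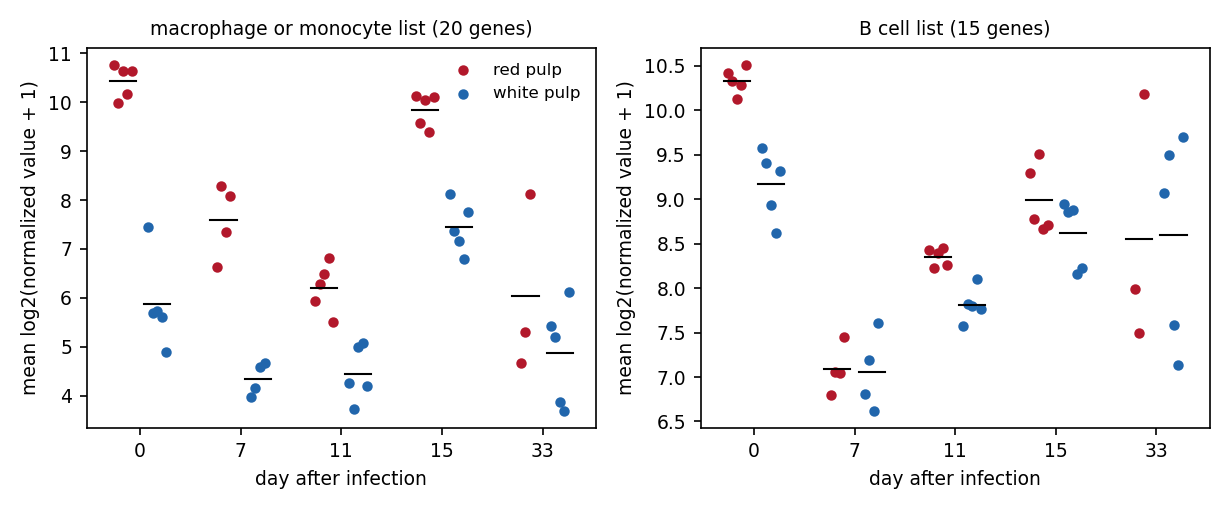
Markers of other spleen cells in the P14 libraries. Each point is 1 library, and its height is the mean log2 level (normalized count + 1) of the tested macrophage and monocyte markers or B cell markers, by day and compartment. Bars mark group means. Red pulp day 0 and day 15 libraries held the highest macrophage scores.

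White pulp day 11 replicate 1 listed 0 for nearly all tested genes of whole chromosome stretches. The stretches were chromosome 9 (590 of 592 tested genes), chromosome X (324 of 327), chromosome Y (4 of 4), chromosome 8 from 95081186 to 129234406 (209 of 210) and chromosome 11 from 32000463 to 48992226 (45 of 49), in GRCm38 coordinates. In all 1172 of 1182 tested genes there (99.2%) were listed at 0 in this library. Cd3e, which encodes a chain of the T cell receptor complex, Cx3cr1, Cxcr3 and Eomes lie in these stretches, and no white pulp day 11 change is given below for single genes of the stretches, although lists include them. The library's median correlation with its group was 0.637 over all tested genes and 0.916 outside the stretches. The values of 0 also widened the spread fitted for these genes in every comparison, as for the chemokine receptor genes Cxcr3 and Cx3cr1 and for Eomes. On day 7 against day 0 Cxcr3 was at 2.44 and 2.75 in white and red pulp (SE 1.17 and 1.17, adjusted p = 0.0993 and 0.0566) and Eomes at 1.36 and 1.75 (SE 0.95 and 0.95, adjusted p = 0.283 and 0.146), and Cx3cr1 rose (7.38 in white, 4.70 in red pulp, SE 1.29, adjusted p up to 0.00331). With the stretches set aside, a choice made after the data were seen, the SE was 0.13 and 0.13 for Cxcr3 (adjusted p = 1.2e-19 and 2.5e-21) and 0.18 and 0.18 for Eomes (adjusted p = 3.6e-08 and 1.0e-10), where other alternatives gave 9.9e-16 to 0.265 and 5.9e-09 to 0.378. For Cx3cr1 the alternatives gave 8.3e-16 to 0.0012 in white and 4.2e-12 to 0.13 in red pulp, where the scores as covariates ended the call. The counts of called genes for day 7 against day 0 were then 4674 in white and 5039 in red pulp, in place of 4222 and 4564, and day 11 against day 0 in white pulp gave 4107 in place of 3995. White against red pulp on day 11 gave 19 called genes in place of 17.

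**Figure D2:**
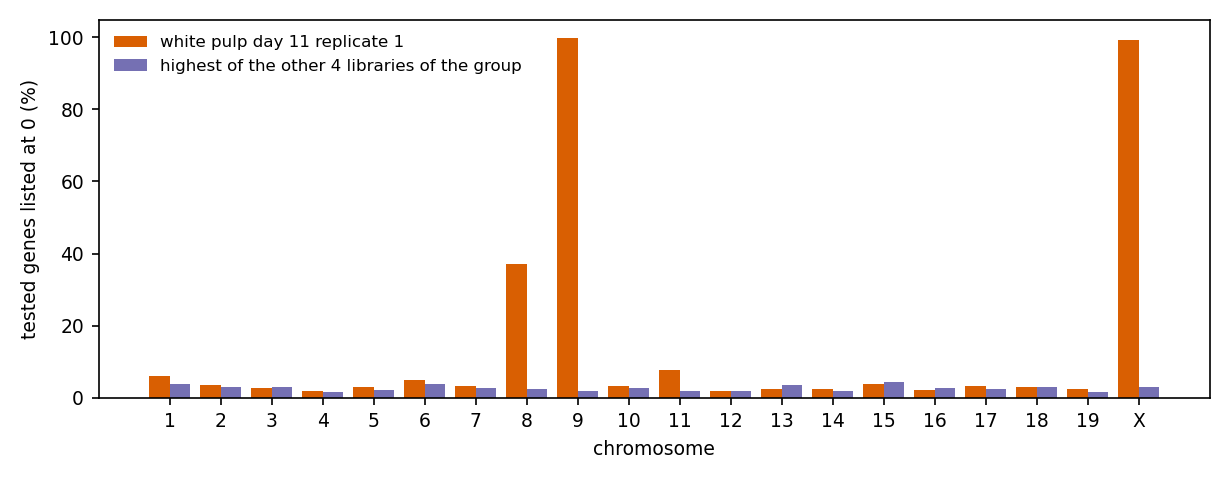
Genes listed at 0 by chromosome. Bars give the percent of tested genes with a value of 0 in white pulp day 11 replicate 1 and the highest percent among the other 4 libraries of that group. Replicate 1 stands apart on chromosomes 8, 9, 11 and X. Chromosome Y is not drawn.

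By day 7 the P14 cells of both compartments had gained the transcripts of cytotoxic effector cells and of cell division and had lost those of naive cells. The granzymes and the chemokine gene Ccl5 rose most clearly, with log2 fold changes for Gzmb, Ccl5, Gzma and Gzmk (8.43, 6.35, 7.92 and 9.13 in white, 8.08, 5.89, 7.20 and 9.86 in red pulp, SE 0.22 to 0.37, adjusted p up to 1.4e-22). Gzmb, which encodes granzyme B, went from 44.5 ± 19.2 normalized counts (n = 5) to 14692 ± 3740.4 (n = 4) in white pulp and from 51.0 ± 16.8 (n = 5) to 13655 ± 2525 (n = 4) in red pulp. The chemokine receptor gene Ccr7 and the transcription factor gene Tcf7 fell (-5.17 and -3.03 in white, -5.38 and -3.19 in red pulp, SE 0.18 to 0.34, adjusted p up to 1.1e-15). Il7r, the interleukin-7 receptor chain, was lower as well (-2.18 in white, -2.42 in red pulp, SE 0.27, adjusted p up to 1.5e-08). Gzmb lies on chromosome 14 (56258838 to 56262260) in GRCm38 coordinates. The largest rises included Nek2 and Ncald (8.92 and 8.79 in white, 9.60 and 8.80 in red pulp, SE 0.28 to 0.60, adjusted p up to 2.5e-15). Among the largest falls were those of Dapl1, Tdrp and Slc6a19 (-7.27, -7.20 and -7.13 in white, -7.76, -8.26 and -6.97 in red pulp, SE 0.53 to 1.08, adjusted p up to 1.5e-06).

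Of 28 tested terminal effector genes, 26 were higher and 0 lower in white pulp and 27 and 0 in red pulp (27 and 0, then 28 and 0 adjusted over the list alone). By camera the adjusted p was 3.5e-31 and 7.9e-27 (4.1e-07 and 2.3e-06 with an estimated correlation). Examples were S100a6, Klrg1 and Id2 (5.47, 8.61 and 3.30 in white, 5.25, 9.56 and 3.04 in red pulp, SE 0.11 to 0.28, adjusted p up to 4.8e-24), of which Klrg1 encodes an inhibitory receptor of terminally differentiated effector cells. Of 21 tested cytotoxic and cytokine genes, 15 were higher and 3 lower in white pulp and 16 and 2 in red pulp (the same counts adjusted over the list alone), where Tnf and Lamp1 were lower in both compartments and Ctsw in white pulp. For this list camera returned adjusted p = 2.0e-13 and 2.0e-13 (2.8e-05 and 2.8e-05 with an estimated correlation). Of 45 tested cell cycle genes, 43 were higher and 0 lower in white pulp and 44 and 0 in red pulp (the same counts adjusted over the list alone). In the list test (camera) adjusted p = 1.4e-29 and 7.2e-29 (0.00318 and 0.00429 with an estimated correlation). They included Hmgb2, Nusap1, Top2a and Stmn1 (3.76, 9.16, 5.67 and 4.54 in white, 3.77, 7.47, 5.05 and 4.17 in red pulp, SE 0.21 to 0.55, adjusted p up to 5.1e-14), and the proliferation marker Mki67 (8.49 in white, 6.70 in red pulp, SE 0.78, adjusted p up to 4.9e-09). Of 27 tested naive and memory precursor genes, 1 was higher and 22 lower in white pulp and 1 and 22 in red pulp (1 and 22, then 1 and 23 adjusted over the list alone). The camera adjusted p was 4.8e-19 and 8.3e-17 (1.3e-06 and 4.6e-06 with an estimated correlation). The exception was Ly6c2, a surface antigen of activated and memory CD8 T cells, which rose (2.94 in white, 3.48 in red pulp, SE 0.12, adjusted p up to 2.8e-22). Of 40 tested transcription factors of T cells, 15 were higher and 10 lower in white pulp and 14 and 12 in red pulp (15 and 11, then 15 and 12 adjusted over the list alone). Camera on this list gave adjusted p = 0.477 and 0.682 (0.615 and 0.738 with an estimated correlation). Tbx21, which encodes T-bet, and Bhlhe40 rose (3.07 and 5.08 in white, 3.73 and 3.33 in red pulp, SE 0.19 to 0.21, adjusted p up to 4.2e-16).

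Receptors changed in both directions. Of 30 tested trafficking receptors, 14 were higher and 9 lower in white pulp and 14 and 11 in red pulp (15 and 10, then 16 and 11 adjusted over the list alone). Camera gave adjusted p = 0.241 and 0.35 (0.514 and 0.561 with an estimated correlation). The integrin genes Itga4 and Itgax (3.33 and 8.78 in white, 2.81 and 5.17 in red pulp, SE 0.10 to 0.38, adjusted p up to 2.7e-14) rose, and Itgae, whose product pairs with integrin beta 7, fell (-4.05 in white, -4.47 in red pulp, SE 0.46, adjusted p up to 2.0e-09). Of 17 tested inhibitory receptor and exhaustion genes, 12 were higher and 2 lower in white pulp and 8 and 3 in red pulp (the same counts adjusted over the list alone), with Btla and Tox among the lower genes in both. By camera the adjusted p was 0.00111 and 0.0678 (0.00265 and 0.0813 with an estimated correlation). Inhibitory receptor genes in red pulp gained the camera call in 1 of 9 fits with 1 library left out (adjusted p = 0.0481 without red pulp day 0 replicate 3). Tigit and Ctla4 (8.28 and 5.93 in white, 6.07 and 6.35 in red pulp, SE 0.55 to 0.78, adjusted p up to 6.2e-08) rose. Of 25 tested cytokine receptors, 10 were higher and 9 lower in white pulp and 8 and 8 in red pulp (10 and 9, then 8 and 9 adjusted over the list alone), and in both the median and the test lay below 0 and the mean above it. For this list camera returned adjusted p = 0.58 and 0.518 (0.687 and 0.625 with an estimated correlation). Il18rap (4.48 in white, 4.75 in red pulp, SE 0.23, adjusted p up to 5.5e-19) was higher and Il27ra and Il6st (-1.76 and -3.21 in white, -1.57 and -3.02 in red pulp, SE 0.11 to 0.20, adjusted p up to 2.6e-15) were lower. Of 26 tested genes higher in tissue-resident cells, 8 were higher and 11 lower in white pulp and 7 and 13 in red pulp (8 and 12, then 7 and 13 adjusted over the list alone). In the list test (camera) adjusted p = 0.199 and 0.0678 (0.353 and 0.129 with an estimated correlation). Of these, Rgs10 and Cd69 (-5.05 and -2.04 in white, -5.05 and -1.82 in red pulp, SE 0.17 to 0.30, adjusted p up to 1.4e-11) fell, Cd69 being an early activation and retention marker. Of 25 tested genes lower in tissue-resident cells, 8 were higher and 10 lower in white pulp and 8 and 10 in red pulp (8 and 10, then 8 and 11 adjusted over the list alone), and in white pulp the median and the test lay below 0 and the mean above it. The camera adjusted p was 0.122 and 0.16 (0.326 and 0.344 with an estimated correlation).

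Genes of energy metabolism rose in part of their lists. Of 20 tested glycolysis genes, 10 were higher and 2 lower in white pulp and 11 and 1 in red pulp (10 and 2, then 13 and 1 adjusted over the list alone). Camera on this list gave adjusted p = 0.00497 and 5.9e-04 (0.107 and 0.0493 with an estimated correlation). The glucose transporter gene Slc2a3 and the phosphofructokinase gene Pfkp rose (1.86 and 1.19 in white, 2.15 and 1.49 in red pulp, SE 0.09 to 0.15, adjusted p up to 3.2e-13). Of 51 tested oxidative phosphorylation genes, 13 were higher and 3 lower in white pulp and 25 and 1 in red pulp (12 and 3, then 25 and 1 adjusted over the list alone). Camera gave adjusted p = 0.0515 and 5.7e-05 (0.615 and 0.344 with an estimated correlation). In white pulp these gained the camera call in 4 of 9 fits with 1 library left out (adjusted p down to 0.00858 without white pulp day 7 replicate 1). Of 22 tested fatty acid oxidation genes, 9 were higher and 3 lower in white pulp and 10 and 2 in red pulp (the same counts adjusted over the list alone). By camera the adjusted p was 0.177 and 0.1 (0.434 and 0.319 with an estimated correlation). Cpt1a, which encodes the enzyme that commits fatty acids to mitochondrial oxidation, was higher (2.27 in white, 1.78 in red pulp, SE 0.24, adjusted p up to 1.4e-07). Of 25 tested cholesterol synthesis genes, 3 were higher and 0 lower in white pulp and 4 and 1 in red pulp (3 and 0, then 2 and 0 adjusted over the list alone). For this list camera returned adjusted p = 0.852 and 0.518 (0.935 and 0.738 with an estimated correlation). Of 32 tested type I interferon response genes, 4 were higher and 16 lower in white pulp and 4 and 12 in red pulp (5 and 19, then 4 and 15 adjusted over the list alone), and the higher genes included Ly6a. In the list test (camera) adjusted p = 5.5e-04 and 0.00481 (0.045 and 0.0872 with an estimated correlation). Rtp4 (-1.77 in white, -1.55 in red pulp, SE 0.18, adjusted p up to 6.6e-09) fell. Of 22 tested T cell receptor response genes, 7 were higher and 12 lower in white pulp and 6 and 11 in red pulp (the same counts adjusted over the list alone). The camera adjusted p was 0.159 and 0.299 (0.434 and 0.551 with an estimated correlation). Of 23 tested dissociation and heat shock genes, 2 were higher and 10 lower in white pulp and 1 and 13 in red pulp (2 and 11, then 1 and 13 adjusted over the list alone). Camera on this list gave adjusted p = 0.00265 and 0.00164 (0.045 and 0.0493 with an estimated correlation). The stress genes Ier5 and Zfp36 (-1.14 and -1.08 in white, -1.15 and -1.30 in red pulp, SE 0.14 to 0.15, adjusted p up to 1.9e-07) fell, whereas the chemokine gene Ccl4 (4.49 in white, 4.56 in red pulp, SE 0.48, adjusted p up to 5.5e-10) rose.

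On day 7 against day 0, limma called 4222 of 11219 tested genes in white pulp (2474 higher, 1748 lower) and 4564 in red pulp (2405 higher, 2159 lower). The compartments shared 1776 higher and 1323 lower genes, where independent lists would share 530.3 and 336. For markers of other cells in the same comparison, macrophage markers were 1 higher and 10 lower of 20 in white pulp and 0 and 19 in red pulp (camera adjusted p = 0.00265 and 9.1e-08, adjusted p = 0.434 and 0.129 with an estimated correlation). B cell markers were 0 higher and 15 lower of 15 in white pulp and 0 and 15 in red pulp (camera adjusted p = 6.2e-08 and 1.8e-12, adjusted p = 0.189 and 0.0813 with an estimated correlation). With the macrophage and B cell scores as covariates, chosen after the data were seen, the red pulp count was 1971 and the white pulp count 2877.

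**Figure D3:**
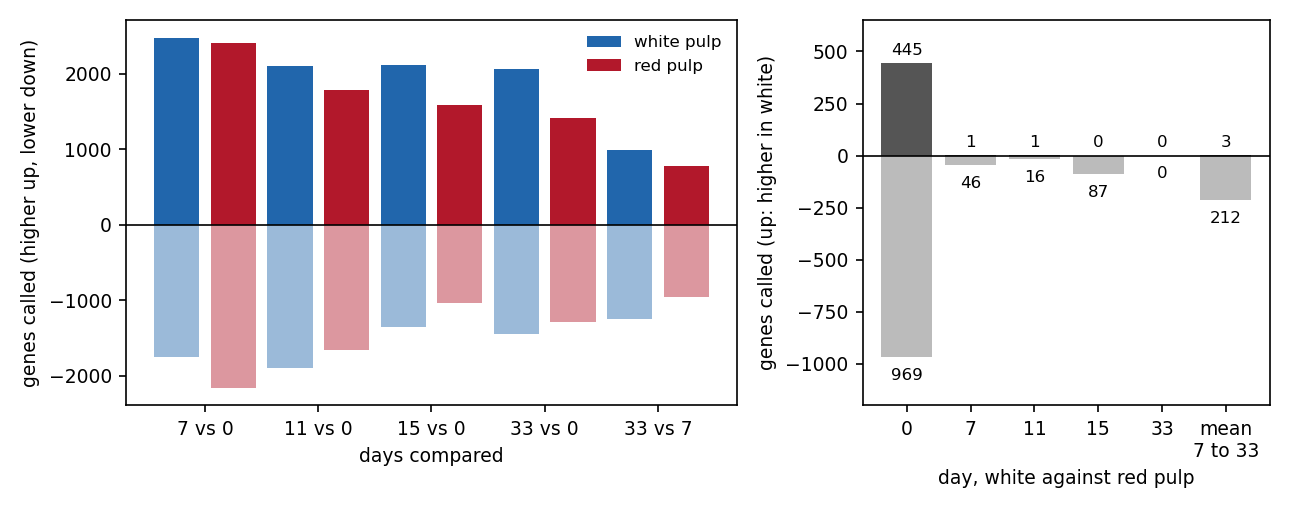
Genes called in each comparison. Left, genes higher (up) and lower (down) on the later day in each compartment. Right, genes higher (up) and lower (down) in white than in red pulp on each day and for the mean of days 7 to 33. Calls are at an adjusted p below 0.05 by limma.

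**Figure D4:**
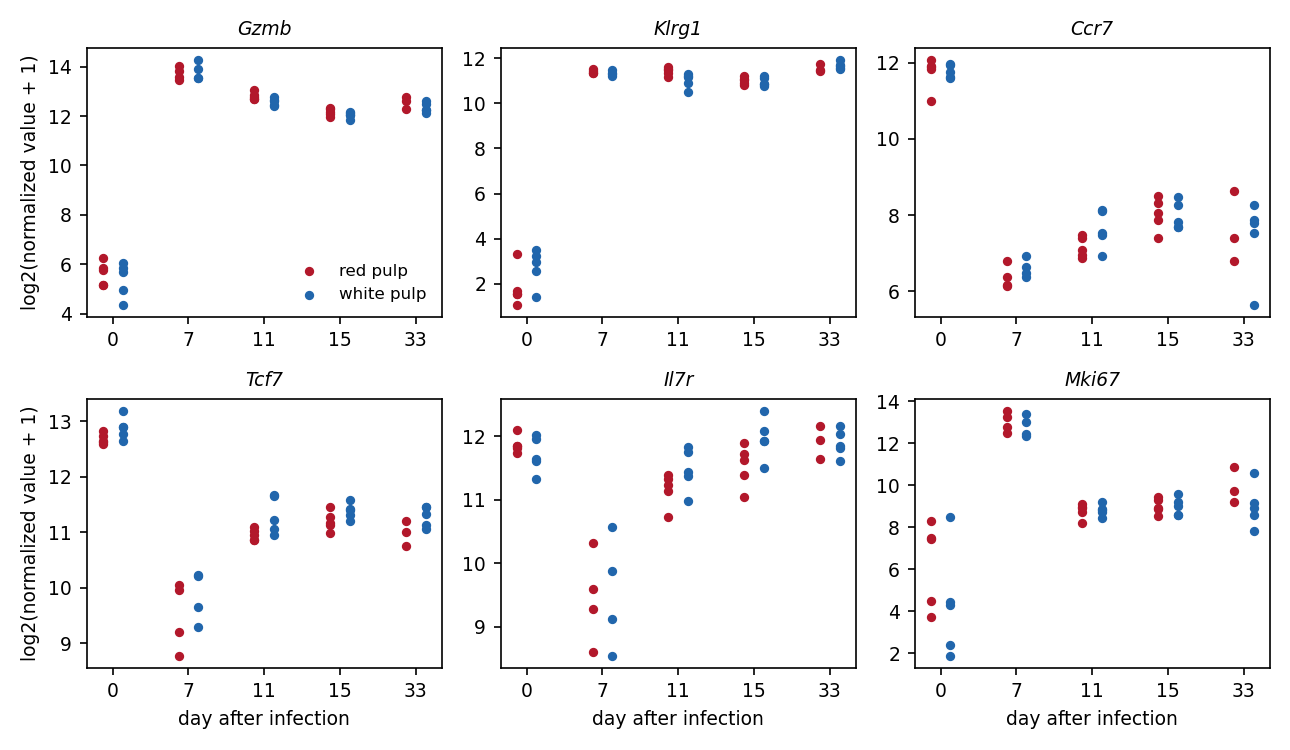
Levels of named genes over time. Each point is 1 library, at its log2 level (normalized count + 1), with red pulp left of white pulp on each day.

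The effector program persisted on day 11 and fewer cell cycle genes were called than on day 7. Granzyme genes and Ccl5 stayed above day 0, with Gzmb, Ccl5 and Gzma (7.19, 7.24 and 7.10 in white, 7.17, 6.84 and 6.79 in red pulp, SE 0.21 to 0.27, adjusted p up to 1.5e-22). The death ligand gene Fasl, Klrg1 and Gzmk were among the largest rises (8.32, 8.28 and 8.19 in white, 8.16, 9.60 and 8.92 in red pulp, SE 0.26 to 0.69, adjusted p up to 2.1e-12). Ampd1 and Ramp1 were among the largest falls (-6.96 and -7.39 in white, -6.86 and -5.63 in red pulp, SE 0.56 to 0.75, adjusted p up to 1.1e-07). Of 28 tested terminal effector genes, 26 were higher and 0 lower in white pulp and 28 and 0 in red pulp (the same counts adjusted over the list alone). Camera gave adjusted p = 5.5e-35 and 1.3e-37 (1.1e-07 and 4.8e-08 with an estimated correlation). Id2 and S100a6 rose again (3.77 and 4.41 in white, 3.63 and 4.40 in red pulp, SE 0.10 to 0.12, adjusted p up to 1.6e-27). Of 27 tested naive and memory precursor genes, 2 were higher and 20 lower in white pulp and 2 and 23 in red pulp (2 and 21, then 2 and 23 adjusted over the list alone). By camera the adjusted p was 2.6e-13 and 2.1e-16 (2.7e-05 and 4.0e-06 with an estimated correlation). Actn1 fell (-3.24 in white, -3.85 in red pulp, SE 0.21, adjusted p up to 8.3e-16). Il7r was at -0.24 in white pulp (SE 0.25, adjusted p = 0.478) and -0.70 in red pulp (SE 0.25, adjusted p = 0.0317). Leaving out 1 library ended the call of Il7r in 3 of 10 cases (0.0975 without red pulp day 11 replicate 4), with the highest adjusted p in parentheses. Of 45 tested cell cycle genes, 26 were higher and 0 lower in white pulp and 26 and 0 in red pulp (28 and 1, then 27 and 0 adjusted over the list alone). For this list camera returned adjusted p = 1.9e-06 and 3.4e-06 (0.301 and 0.224 with an estimated correlation). Nusap1 and Top2a were still higher (4.73 and 2.27 in white, 3.51 and 1.84 in red pulp, SE 0.33 to 0.52, adjusted p up to 2.0e-05). The integrin gene Itga1 and the transcription factor genes Bhlhe40 and Tbx21 rose (6.75, 5.48 and 3.30 in white, 5.93, 3.82 and 4.13 in red pulp, SE 0.18 to 0.54, adjusted p up to 1.4e-11). Rgs10 and Cd69 fell (-4.54 and -1.91 in white, -4.33 and -1.79 in red pulp, SE 0.16 to 0.29, adjusted p up to 6.0e-12). The receptor genes Il18rap and Tigit (4.52 and 6.34 in white, 5.03 and 4.23 in red pulp, SE 0.22 to 0.52, adjusted p up to 1.8e-08) rose, and Il6st (-2.91 in white, -2.88 in red pulp, SE 0.19, adjusted p up to 1.3e-15) fell.

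On day 11 against day 0, limma called 3995 of 11219 tested genes in white pulp (2098 higher, 1897 lower) and 3446 in red pulp (1789 higher, 1657 lower). The compartments shared 1150 higher and 987 lower genes, where independent lists would share 335 and 280.2. Of other cells, macrophage markers were 1 higher and 13 lower of 20 in white pulp and 0 and 18 in red pulp (camera adjusted p = 0.00362 and 2.1e-16, adjusted p = 0.375 and 0.0352 with an estimated correlation). B cell markers were 0 higher and 13 lower of 15 in white pulp and 0 and 15 in red pulp (camera adjusted p = 1.4e-04 and 9.3e-09, adjusted p = 0.34 and 0.159 with an estimated correlation). NK, neutrophil and erythroid scores mostly rose. Covariates left 969 red pulp genes and the groups alone 2346 in white.

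On day 15 most terminal effector genes were above and most naive and memory precursor genes below day 0. Ccl5, Gzmb and Gzma (7.16, 6.66 and 7.05 in white, 6.55, 6.51 and 6.26 in red pulp, SE 0.21 to 0.27, adjusted p up to 2.7e-21) rose. The largest rises in both compartments included Ncald, Klrg1 and Fasl (8.23, 8.22 and 8.22 in white, 8.45, 9.17 and 7.96 in red pulp, SE 0.26 to 0.69, adjusted p up to 5.8e-12). Among the largest falls were Ampd1 and Ccr9 (-6.52 and -6.02 in white, -6.58 and -5.72 in red pulp, SE 0.56 to 0.80, adjusted p up to 4.2e-07), Ccr9 being a gut homing receptor. Of 28 tested terminal effector genes, 27 were higher and 0 lower in white pulp and 27 and 0 in red pulp (28 and 0, then 28 and 0 adjusted over the list alone). In the list test (camera) adjusted p = 2.0e-39 and 3.3e-42 (2.7e-08 and 1.2e-08 with an estimated correlation). Of 27 tested naive and memory precursor genes, 3 were higher and 21 lower in white pulp and 2 and 22 in red pulp (3 and 22, then 2 and 22 adjusted over the list alone). The camera adjusted p was 5.6e-15 and 2.0e-19 (9.3e-06 and 6.9e-07 with an estimated correlation). Actn1 (-3.04 in white, -2.70 in red pulp, SE 0.21, adjusted p up to 2.9e-13) fell, and Klf2 (0.68 in white, 0.58 in red pulp, SE 0.15, adjusted p up to 0.00354) rose. Il7r was at 0.25 (SE 0.25, adjusted p = 0.508) in white and -0.33 (SE 0.25, adjusted p = 0.397) in red pulp. Of 45 tested cell cycle genes, 26 were higher and 0 lower in white pulp and 23 and 0 in red pulp (28 and 0, then 27 and 0 adjusted over the list alone). Camera on this list gave adjusted p = 1.0e-06 and 8.5e-06 (0.235 and 0.277 with an estimated correlation). Rtp4 and Ifi27l2a fell in both compartments (-1.72 and -1.95 in white, -1.51 and -2.03 in red pulp, SE 0.17 to 0.21, adjusted p up to 6.7e-09). Of 8 tested NK cell markers, 7 were higher and 0 lower in white pulp and 4 and 0 in red pulp (7 and 0, then 5 and 0 adjusted over the list alone). Camera gave adjusted p = 2.3e-08 and 7.7e-05 (1.2e-05 and 0.00132 with an estimated correlation). Klrb1c, which encodes the receptor NK1.1, and Klra3 rose (8.29 and 4.57 in white, 5.88 and 4.17 in red pulp, SE 0.49 to 0.52, adjusted p up to 4.0e-08). Itgal, an integrin chain of LFA-1, and Id2 rose as well (1.62 and 3.53 in white, 1.54 and 3.19 in red pulp, SE 0.10 to 0.11, adjusted p up to 2.9e-14).

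On day 15 against day 0, limma called 3456 of 11219 tested genes in white pulp (2107 higher, 1349 lower) and 2632 in red pulp (1590 higher, 1042 lower). The compartments shared 1109 higher and 735 lower genes, where independent lists would share 299 and 125. For other cells, macrophage markers were 8 higher and 1 lower of 20 in white pulp and 1 and 1 in red pulp (camera adjusted p = 0.0132 and 0.0718, adjusted p = 0.539 and 0.582 with an estimated correlation). Neutrophil markers were 9 higher and 0 lower of 10 in white pulp and 4 and 0 in red pulp (camera adjusted p = 7.4e-04 and 0.0209, adjusted p = 0.235 and 0.432 with an estimated correlation). Erythroid markers were 9 higher and 0 lower of 12 in white pulp and 7 and 0 in red pulp (camera adjusted p = 7.9e-04 and 0.00148, adjusted p = 0.235 and 0.277 with an estimated correlation). In white pulp macrophage markers lost the camera call in 1 of 10 fits with 1 library left out (adjusted p = 0.0533 without white pulp day 0 replicate 5) and in red pulp they gained it in 1 of 10 fits (0.0494 without red pulp day 0 replicate 2). The covariates, chosen after the data were seen, left 2129 called genes in white pulp and 1924 in red pulp.

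On day 33, most cytotoxic and terminal effector genes were still above and most naive genes below day 0. Gzmb, Ccl5 and Gzma (6.97, 7.02 and 7.64 in white, 6.92, 6.34 and 6.78 in red pulp, SE 0.21 to 0.31, adjusted p up to 3.1e-20) rose, and Klrg1, Fasl and Kcnj8 (8.93, 8.42 and 8.36 in white, 9.71, 7.99 and 8.12 in red pulp, SE 0.26 to 0.80, adjusted p up to 2.8e-10) were among the largest rises shared by the compartments. Lef1 and Actn1 (-2.06 and -2.88 in white, -1.92 and -3.43 in red pulp, SE 0.14 to 0.24, adjusted p up to 2.9e-12) fell, Lef1 being a partner of Tcf7 in naive and memory T cells. Il7r was at 0.18 (SE 0.25, adjusted p = 0.66) in white and 0.05 (SE 0.29, adjusted p = 0.943) in red pulp, and at -0.07 in red pulp without red pulp day 33 replicate 4. Of 21 tested cytotoxic and cytokine genes, 18 were higher and 0 lower in white pulp and 16 and 2 in red pulp (18 and 3, then 17 and 2 adjusted over the list alone). By camera the adjusted p was 5.7e-19 and 4.0e-20 (1.2e-06 and 6.5e-07 with an estimated correlation). Of 28 tested terminal effector genes, 27 were higher and 0 lower in white pulp and 26 and 0 in red pulp (27 and 0, then 28 and 0 adjusted over the list alone). For this list camera returned adjusted p = 1.4e-41 and 3.0e-40 (1.4e-08 and 2.1e-08 with an estimated correlation). Klrk1, S100a6 and Id2 (6.18, 4.51 and 3.68 in white, 4.96, 4.37 and 3.49 in red pulp, SE 0.10 to 0.19, adjusted p up to 3.4e-23) were among them. Of 27 tested naive and memory precursor genes, 2 were higher and 21 lower in white pulp and 1 and 21 in red pulp (3 and 21, then 2 and 21 adjusted over the list alone). In the list test (camera) adjusted p = 2.8e-17 and 1.4e-17 (2.3e-06 and 2.1e-06 with an estimated correlation). Of 45 tested cell cycle genes, 27 were higher and 0 lower in white pulp and 28 and 0 in red pulp (28 and 1, then 32 and 0 adjusted over the list alone). The camera adjusted p was 6.3e-08 and 1.3e-10 (0.182 and 0.106 with an estimated correlation). Ifi27l2a and Rtp4 again fell (-2.55 and -2.02 in white, -2.85 and -1.71 in red pulp, SE 0.17 to 0.25, adjusted p up to 9.9e-09), and Tox, a regulator of exhausted T cells, fell too (-2.62 in white, -2.62 in red pulp, SE 0.47 to 0.54, adjusted p up to 2.5e-04).

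On day 33 against day 0, limma called 3502 of 11219 tested genes in white pulp (2055 higher, 1447 lower) and 2701 in red pulp (1407 higher, 1294 lower). The compartments shared 1048 higher and 782 lower genes, where independent lists would share 258 and 167. As to other cells, macrophage markers were 1 higher and 7 lower of 20 in white pulp and 0 and 18 in red pulp (camera adjusted p = 0.00892 and 6.6e-18, adjusted p = 0.523 and 0.0241 with an estimated correlation). B cell markers were 0 higher and 0 lower of 15 in white pulp and 0 and 14 in red pulp (camera adjusted p = 0.0329 and 1.8e-07, adjusted p = 0.662 and 0.198 with an estimated correlation). In white pulp B cell markers lost the camera call in 4 of 10 fits with 1 library left out (adjusted p up to 0.348 without white pulp day 33 replicate 4) and macrophage markers lost it in 1 of 10 fits (0.104 without white pulp day 0 replicate 1). The covariates left 719 genes in red pulp.

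Between day 7 and day 33 cell cycle genes and part of the glycolysis and oxidative phosphorylation genes fell, and part of the naive and memory genes rose. Il7r, the survival gene Bcl2 and Tcf7 rose in both compartments (2.36, 1.94 and 1.43 in white, 2.47, 1.97 and 1.49 in red pulp, SE 0.18 to 0.31, adjusted p up to 2.7e-06). Il7r went from 849 ± 509 (n = 4) to 3836 ± 564 (n = 5) normalized counts in white pulp and from 764 ± 378 (n = 4) to 3904 ± 701 (n = 3) in red pulp. Of 27 tested naive and memory precursor genes, 10 were higher and 3 lower in white pulp and 9 and 3 in red pulp (12 and 3, then 9 and 3 adjusted over the list alone), with Slamf6 and Myb among the lower genes. Camera on this list gave adjusted p = 0.00135 and 0.0126 (0.0778 and 0.241 with an estimated correlation). In red pulp these lost the camera call in 1 of 7 fits with 1 library left out (adjusted p = 0.102 without red pulp day 33 replicate 5). Of 45 tested cell cycle genes, 0 were higher and 44 lower in white pulp and 0 and 41 in red pulp (0 and 44, then 0 and 43 adjusted over the list alone). Camera gave adjusted p = 3.0e-35 and 3.4e-28 (0.0054 and 0.0194 with an estimated correlation). Hmgb2, Cenpa and Kif20a (-2.13, -3.04 and -2.03 in white, -1.89, -2.86 and -1.84 in red pulp, SE 0.21 to 0.38, adjusted p up to 6.2e-06) fell. Of 20 tested glycolysis genes, 2 were higher and 7 lower in white pulp and 2 and 8 in red pulp (2 and 9, then 2 and 8 adjusted over the list alone). By camera the adjusted p was 5.0e-04 and 0.00123 (0.056 and 0.129 with an estimated correlation). Gapdh and Ldha (-1.44 and -1.07 in white, -1.43 and -1.01 in red pulp, SE 0.13 to 0.15, adjusted p up to 5.8e-06) fell. Of 51 tested oxidative phosphorylation genes, 0 were higher and 27 lower in white pulp and 0 and 25 in red pulp (1 and 32, then 0 and 28 adjusted over the list alone). For this list camera returned adjusted p = 1.2e-12 and 1.1e-13 (0.108 and 0.168 with an estimated correlation). Atp5a1 and Uqcrfs1 (-0.78 and -1.02 in white, -0.78 and -0.96 in red pulp, SE 0.08 to 0.14, adjusted p up to 4.5e-06) were examples.

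Klre1, an NK cell receptor gene, rose (3.17 in white, 2.95 in red pulp, SE 0.38 to 0.43, adjusted p up to 4.6e-06), and Gzmb (-1.46 in white, -1.16 in red pulp, SE 0.22 to 0.25, adjusted p up to 9.6e-04) fell. Of 17 tested inhibitory receptor and exhaustion genes, 2 were higher and 4 lower in white pulp and 0 and 3 in red pulp (2 and 4, then 1 and 3 adjusted over the list alone), and in red pulp the median lay above 0 while the mean and the test were below. In the list test (camera) adjusted p = 0.407 and 0.405 (0.44 and 0.376 with an estimated correlation). On day 33 against day 7, limma called 2235 of 11219 tested genes in white pulp (984 higher, 1251 lower) and 1742 in red pulp (783 higher, 959 lower). The compartments shared 526 higher and 784 lower genes, where independent lists would share 68.7 and 107. Among other cells, B cell markers were 12 higher and 0 lower of 15 in white pulp and 6 and 0 in red pulp (camera adjusted p = 1.3e-07 and 1.8e-06, adjusted p = 0.178 and 0.336 with an estimated correlation). Macrophage markers were 1 higher and 1 lower of 20 in white pulp and 0 and 3 in red pulp (camera adjusted p = 0.294 and 6.4e-04, adjusted p = 0.763 and 0.338 with an estimated correlation). In red pulp they lost the camera call in 1 of 7 fits with 1 library left out (adjusted p = 0.0879 without red pulp day 33 replicate 3). The red pulp count was 1093 without red pulp day 33 replicate 4 and 488 with the scores as covariates, and library quality weights gave 3611 in white and 3606 in red pulp.

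**Figure D5:**
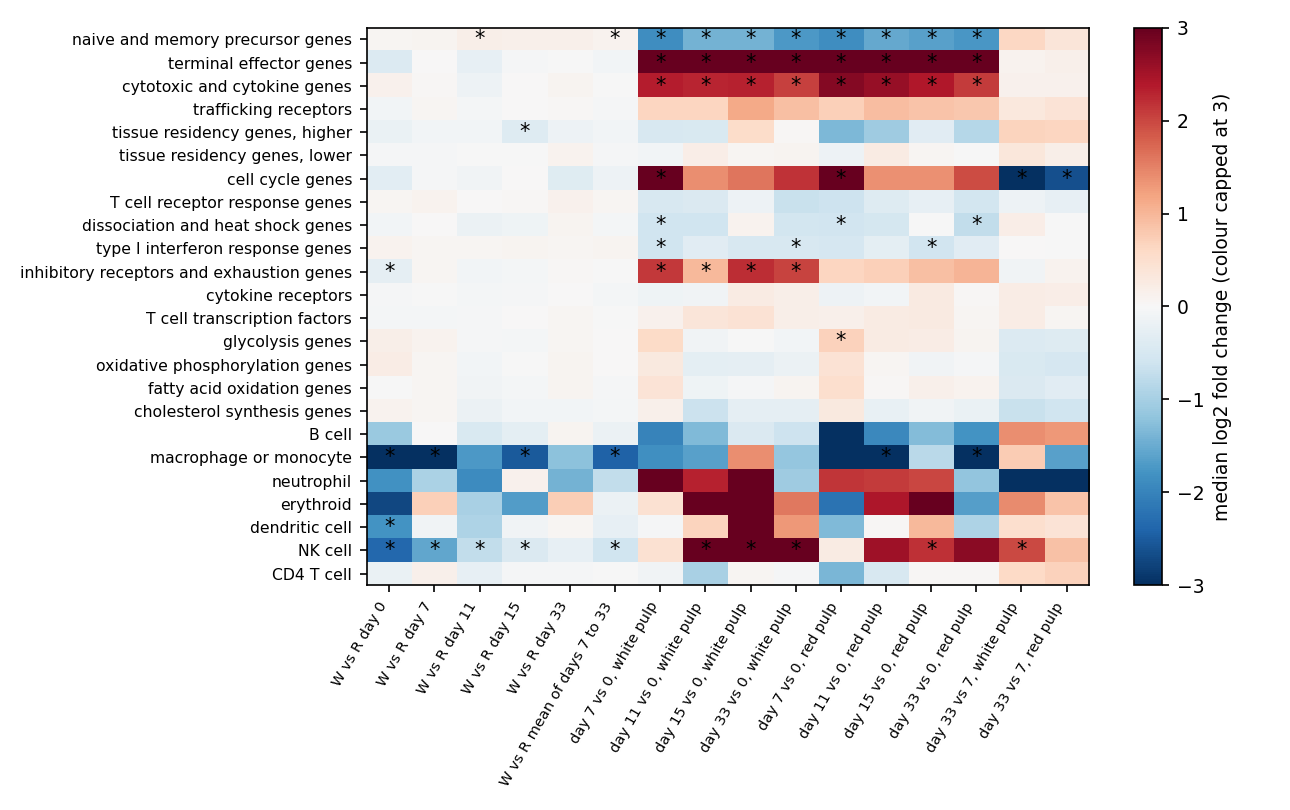
Gene lists over time. Each cell gives the median log2 fold change of the tested members of a fixed list in a comparison (W, white pulp, R, red pulp). Asterisks mark an adjusted p below 0.05 by camera with an estimated correlation.

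On day 0 the compartments differed in many genes, and the largest differences were genes of macrophages that were lower in white pulp. White pulp libraries had less of Cd68, Axl, C1qb and Csf1r (-3.91, -4.59, -4.63 and -4.86, SE 0.30 to 0.60, adjusted p up to 1.4e-07). Mertk, Adamdec1 and Adrbk2 (-7.98, -7.27 and -7.22, SE 0.95 to 1.06, adjusted p up to 3.7e-06) were among the largest falls, Mertk being a macrophage receptor for apoptotic cells. Pla2g6, Spopl and Pex14 (2.39, 1.78 and 1.44, SE 0.30 to 0.58, adjusted p up to 0.00398) were among the genes highest in white relative to red pulp. Cd8a, which encodes the coreceptor of the sorted cells, was 0.40 higher (SE 0.06, adjusted p = 1.8e-06), at 6352 ± 679 against 4789.6 ± 169.6 normalized counts. Among T cell lists, 4 of 28 terminal effector genes were higher and 11 lower (5 and 12 adjusted over the list alone, median log2 fold change -0.42, camera adjusted p = 5.7e-04, adjusted p = 0.0907 with an estimated correlation). The lower ones included Zeb2, Lgals3 and Bhlhe40 (-3.99, -4.12 and -1.75, SE 0.20 to 0.34, adjusted p up to 2.8e-08), genes that macrophages also express, and Tbx21 (0.71, SE 0.18, adjusted p = 0.00454) and Klrg1 (0.89, SE 0.26, adjusted p = 0.019) were higher. As to inhibitory receptors, 1 of 17 genes was higher and 6 lower (1 and 7 adjusted over the list alone, median log2 fold change -0.27, camera adjusted p = 0.0218, adjusted p = 0.0453 with an estimated correlation), with Entpd1 and Lilrb4 (-4.87 and -2.64, SE 0.33 to 0.51, adjusted p up to 2.3e-07) lower and Pdcd1 (3.21, SE 0.49, adjusted p = 6.3e-06) higher. For naive and memory precursor genes, 2 of 27 genes were higher and 0 lower (1 and 0 adjusted over the list alone, median log2 fold change 0.06, camera adjusted p = 0.105, adjusted p = 0.4 with an estimated correlation), and Ly6c2 and S1pr1 (0.61 and 0.21, SE 0.07 to 0.11, adjusted p up to 0.0466) were higher. The list gained the camera call in 1 of 10 fits with 1 library left out (adjusted p = 0.0408 without red pulp day 0 replicate 3). Leaving out 1 library ended the calls of Klrg1 in 3 of 10 cases (0.0837 without red pulp day 0 replicate 2) and S1pr1 in 8 (0.176 without white replicate 3), with the highest adjusted p in parentheses. Tcf7 was at 0.19 (SE 0.17, adjusted p = 0.55). For oxidative phosphorylation, 5 of 51 genes were higher and 0 lower (5 and 0 adjusted over the list alone, median log2 fold change 0.22, camera adjusted p = 2.9e-06, adjusted p = 0.356 with an estimated correlation), Atp5a1 and Cox8a (0.43 and 0.43, SE 0.07 to 0.11, adjusted p up to 0.00797) being the examples.

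On day 0, 1414 of 11219 tested genes passed limma's test, 445 higher and 969 lower in white pulp. The macrophage score was higher in red pulp in the same libraries (above), and with the macrophage and B cell scores as covariates the count was 58 (9 higher, 49 lower). Quality weights gave 616 genes (55 higher, 561 lower) and a fit to the day 0 libraries alone 383 (18 higher, 365 lower), so most of the calls of higher genes were lost. The calls of Pla2g6, Spopl, Pex14, Tbx21, Klrg1, Pdcd1, S1pr1 and Cox8a ended in the fit to the day 0 libraries alone, and those of Pex14, Tbx21, Klrg1 and S1pr1 with quality weights.

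On day 7 the genes called lower in white pulp were again led by macrophage genes. Pira2, Mrc1, Emr1, Vcam1, Slc40a1 and C1qa (-5.43, -5.30, -5.18, -4.58, -4.43 and -4.39, SE 0.59 to 0.94, adjusted p up to 0.00128) were among the largest falls. C1qb and Hpgds (-3.34 and -4.50, SE 0.57 to 0.75, adjusted p up to 8.8e-04) and Tyrobp and Fcer1g (-1.91 and -1.89, SE 0.34 to 0.40, adjusted p up to 0.0113) fell too. Emr1 encodes the macrophage marker F4/80 and Slc40a1 the iron exporter ferroportin. Tnfsf8, which encodes CD30 ligand, was the gene called higher, by 2.62 (SE 0.62, adjusted p = 0.044). Leaving out 1 library ended the calls of Tnfsf8 in 6 of 8 cases (0.258 without red pulp day 7 replicate 1) and Fcer1g in 3 (0.0628 without red replicate 5), with the highest adjusted p in parentheses. Of the lists, 0 of 20 macrophage and monocyte markers were higher and 11 lower (0 and 19 adjusted over the list alone, median log2 fold change -3.70, camera adjusted p = 1.8e-58, adjusted p = 3.3e-05 with an estimated correlation). For the naive list, 0 of 27 naive and memory precursor genes were higher and 0 lower (0 and 0 adjusted over the list alone, median log2 fold change 0.08, camera adjusted p = 0.163, adjusted p = 0.733 with an estimated correlation). This list gained the camera call in 1 of 8 fits with 1 library left out (adjusted p = 0.0324 without red pulp day 7 replicate 1). Limma called 47 of 11219 tested genes, 1 higher and 46 lower. The count was 30 without white pulp day 7 replicate 3 and 28 and 23 without red pulp day 7 replicate 3 or 5, and it was 256 with quality weights, 75 by DESeq2 and 0 with the scores as covariates.

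On day 11 few genes were called. Ifitm3, Kctd12, Fcer1g, Gngt2 and Mrc1 (-2.45, -1.74, -1.72, -1.62 and -4.15, SE 0.36 to 0.84, adjusted p up to 0.0426) were lower in white pulp, Mrc1 encoding the macrophage mannose receptor. Miat, a noncoding RNA gene named after its value was seen, was the gene called higher (2.46, SE 0.45, adjusted p = 0.00766). Leaving out 1 library ended the calls of Ifitm3 in 5 of 10 cases (0.148 without red pulp day 11 replicate 4), Kctd12 in 8 (0.238 without red replicate 4), Fcer1g in 7 (0.148 without red replicate 4), Gngt2 in 9 (0.148 without red replicate 4), Mrc1 in 5 (0.091 without white replicate 5) and Miat in 2 (0.0672 without red replicate 1), with the highest adjusted p in parentheses. In the lists, 0 of 20 macrophage and monocyte markers were higher and 1 lower (0 and 13 adjusted over the list alone, median log2 fold change -1.72, camera adjusted p = 1.4e-15, adjusted p = 0.0616 with an estimated correlation). For the naive list, 0 of 27 naive and memory precursor genes were higher and 0 lower (1 and 0 adjusted over the list alone, median log2 fold change 0.17, camera adjusted p = 9.2e-05, adjusted p = 0.0324 with an estimated correlation). The terminal effector list gave a camera adjusted p = 0.00177 in the lower direction (adjusted p = 0.217 with an estimated correlation), with 0 of 28 genes called. Of its members 6 lie in the missing stretches, and its mean log2 difference of -0.67 was -0.15 without white pulp day 11 replicate 1 (adjusted p = 0.0137). It was -0.20 over the members outside the stretches, a choice made after the data were seen (adjusted p = 0.00308, and 0.0883 with an estimated correlation). limma called 17 of 11219 tested genes, 1 higher and 16 lower. The count was 7, 11 and 2 without white pulp day 11 replicate 2, 4 or 5 and 5, 8, 5 and 6 without red pulp day 11 replicate 1, 2, 3 or 4. It was 72 with quality weights, 7 by edgeR, 64 by DESeq2, 42 with the replicate block and 0 with the scores as covariates.

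On day 15 the genes called were all lower in white pulp. Lima1, Paqr9, Col14a1 and Tbxas1 (-4.92, -4.43, -3.99 and -3.79, SE 0.90 to 1.08, adjusted p up to 0.0285) were among the largest falls. Macrophage genes Ctss, Cd68, C1qb and Axl (-1.15, -1.71, -2.76 and -2.09, SE 0.19 to 0.51, adjusted p up to 0.00385) and the adaptor genes Tyrobp and Fcer1g (-1.76 and -2.01, SE 0.30 to 0.36, adjusted p up to 0.00112) were lower. The immediate early genes Nr4a1 and Dusp1 (-1.87 and -1.86, SE 0.39 to 0.42, adjusted p up to 0.0192) and the regulator Rgs2 (-1.34, SE 0.34, adjusted p = 0.0429) were lower, and so were the lysosomal genes Lamp1, Ctsc and Lipa (-0.47, -0.54 and -0.69, SE 0.11 to 0.16, adjusted p up to 0.0429). Leaving out 1 library ended the calls of Lima1 in 4 of 10 cases (0.076 without white pulp day 15 replicate 4), Paqr9 in 2 (0.0563 without white replicate 4), Col14a1 in 5 (0.0957 without white replicate 4), Tbxas1 in 6 (0.187 without white replicate 4), Nr4a1 in 2 (0.0649 without white replicate 4), Dusp1 in 2 (0.0974 without red replicate 5), Rgs2 in 8 (0.261 without white replicate 4), Lamp1 in 4 (0.108 without red replicate 5), Ctsc in 10 (0.145 without white replicate 3) and Lipa in 7 (0.0977 without red replicate 1), with the highest adjusted p in parentheses. Among the lists, 0 of 20 macrophage and monocyte markers were higher and 10 lower (0 and 20 adjusted over the list alone, median log2 fold change -2.52, camera adjusted p = 2.7e-43, adjusted p = 7.4e-04 with an estimated correlation). For genes higher in tissue-resident cells, 0 of 26 genes were higher and 2 lower (0 and 6 adjusted over the list alone, median log2 fold change -0.38, camera adjusted p = 0.00237, adjusted p = 0.0209 with an estimated correlation). Dissociation and heat shock genes, which handling of cells raises, moved the same way, as 0 of 23 genes were higher and 1 lower (0 and 2 adjusted over the list alone, median log2 fold change -0.13, camera adjusted p = 0.0392, adjusted p = 0.203 with an estimated correlation). These lost the camera call in 6 of 10 fits with 1 library left out (adjusted p up to 0.159 without red replicate 3). Macrophage RNA may contribute to the residency list. For naive and memory precursor genes, 0 of 27 genes were higher and 0 lower (0 and 0 adjusted over the list alone, median log2 fold change 0.15, camera adjusted p = 0.00237, adjusted p = 0.101 with an estimated correlation). limma called 87 of 11219 genes, all lower. The count was 52, 31 and 56 without white replicate 3, 4 or 5. It was 36, 51, 49 and 35 without red replicate 1, 2, 3 or 5. It was 256 with a pseudocount of 5, 146 with a minimum mean of 1, 134 with the replicate block, 368 with quality weights, 133 by DESeq2, 396 with the day 15 libraries alone and 0 with the scores as covariates.

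On day 33 no gene passed the test between the compartments. limma called 0 of 11219 genes, edgeR 0 and DESeq2 0, and 262 genes had an unadjusted p below 0.05 by limma. Without red pulp day 33 replicate 5 the count was 1, with quality weights 1 and with a minimum mean of 1 it was 2. With all libraries Tcf7 was at 0.30 (SE 0.20, adjusted p = 1). The lists gave calls by camera, where 0 of 27 naive and memory precursor genes were higher and 0 lower (0 and 0 adjusted over the list alone, median log2 fold change 0.14, camera adjusted p = 0.00127, adjusted p = 0.241 with an estimated correlation). Further, 0 of 45 cell cycle genes were higher and 0 lower (0 and 0 adjusted over the list alone, median log2 fold change -0.36, camera adjusted p = 6.7e-06, adjusted p = 0.42 with an estimated correlation). Last, 0 of 20 macrophage and monocyte markers were higher and 0 lower (0 and 0 adjusted over the list alone, median log2 fold change -1.22, camera adjusted p = 1.5e-11, adjusted p = 0.248 with an estimated correlation). Naive genes lost the camera call in 1 of 8 fits with 1 library left out (adjusted p = 0.112 without red pulp day 33 replicate 3). Cell cycle genes lost it in 1 of 8 fits (0.404 without red pulp day 33 replicate 3). Macrophage markers lost it in 1 of 8 fits (0.708 without red pulp day 33 replicate 5).

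Averaged over days 7 to 33, macrophage and monocyte genes were lower in white pulp, and few genes were higher. Among the genes called higher were Tnfsf8 (1.07, SE 0.30, adjusted p = 0.0492) and Socs1, named after its value was seen (0.38, SE 0.09, adjusted p = 0.0119), a suppressor of cytokine signaling. Mrc1, Fpr1, Cd5l, Igf1, Cd300e and Mertk (-3.62, -3.39, -3.28, -3.15, -3.09 and -3.09, SE 0.41 to 0.65, adjusted p up to 0.00306) were among the largest falls. Also lower were C1qb, Vcam1 and Csf1r (-2.41, -2.74 and -2.49, SE 0.27 to 0.32, adjusted p up to 2.2e-06), Tyrobp and Fcer1g (-1.37 and -1.51, SE 0.16 to 0.19, adjusted p up to 1.6e-06) and Hpgds, Rgs2, Nr4a1 and Dusp1 (-1.83, -0.85, -0.91 and -0.94, SE 0.18 to 0.36, adjusted p up to 0.012). The lists showed that 1 of 27 naive and memory precursor genes was higher and 0 lower (2 and 0 adjusted over the list alone, median log2 fold change 0.10, camera adjusted p = 2.2e-08, adjusted p = 0.00103 with an estimated correlation). In addition 0 of 20 macrophage and monocyte markers were higher and 18 lower (0 and 20 adjusted over the list alone, median log2 fold change -2.42, camera adjusted p = 2.7e-71, adjusted p = 7.3e-06 with an estimated correlation). Klrg1, Gzmb and Tcf7 were at -0.11, -0.12 and 0.29 (adjusted p = 1, 1 and 0.122). Tcf7 was called with quality weights (adjusted p = 4.5e-04) and with the replicate block (adjusted p = 0.00959), where the alternatives gave 4.5e-04 to 0.964. Leaving out 1 library ended the calls of Tnfsf8 in 29 of 36 cases (0.133 without red pulp day 33 replicate 4) and Dusp1 in 1 (0.0502 without red pulp day 33 replicate 5), with the highest adjusted p in parentheses, and Tcf7 was called without white pulp day 7 replicate 5 or red pulp day 7 replicate 1 or 4 (adjusted p from 0.0313 to 0.0386). limma called 215 of 11219 tested genes, 3 higher and 212 lower, and 191 of the lower genes were also lower on day 0. The count was 381 with quality weights and 0 with the macrophage and B cell scores as covariates.

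The difference between the compartments depended on the day for 165 of 11219 tested genes (limma F test). The terms against day 0 were called for 111 genes on day 7, 382 on day 11, 80 on day 15 and 210 on day 33, and 103, 252, 67 and 202 of these moved toward white pulp. Zeb2, a transcription factor of terminal effector cells that macrophages also express, was -3.99 in white relative to red pulp on day 0 and moved by 3.94 toward white pulp on day 7 (F test adjusted p = 2.3e-08). The macrophage gene Cd68 and the integrin gene Itgax gave differences of 3.56 and 3.61 on day 7 (F test adjusted p = 1.2e-06 and 4.2e-06). Pdcd1, which encodes PD-1, and Cd8a moved the other way, by -3.11 and -0.39 on day 7 (F test adjusted p = 0.00754 and 0.00393). In white pulp Zeb2 stood at 17.7 ± 13.9 on day 0 and 616 ± 175 on day 7, and in red pulp at 229 ± 41.3 and 625 ± 125 normalized counts. Without red pulp day 33 replicate 5 the count was 251, edgeR called 101 and DESeq2 290, and the scores as covariates left 55.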

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

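Chosen after the results were seen were the tests of scaling, of the genes at 0 and of every explanation for white pulp day 11 replicate 1, and the fit with the macrophage and B cell scores. White pulp day 11 replicate 1 held 10908 genes above 0, where the others of its group held 12515 to 12781. Values missing for whole chromosome stretches may account for this, since with stretches drawn from every second expressed gene, 526 of the 544 genes at 0 among the genes left out (96.7%) lay in them, against 11.2% of all genes left out. Low depth met a first criterion, as its 5509752 reads were the fewest of its group (the next held 5535363), but a stricter test argues against it: the 17 libraries with fewer reads listed at most 247 genes at 0 that their group expresses, where it listed 1096. As day 11 compartments differ little, a median correlation of 0.916 outside the stretches (others from 0.836) cannot exclude a mislabelled or mixed sample. Whether reads were missing or values were lost in the table stays open, and no biological explanation was tested.

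Red pulp day 7 replicate 1 held 11656 genes above 0, where the others of its group held 13245 to 13451. Red pulp day 15 replicate 1 held 13013 genes above 0, where the others of its group held 13391 to 13482. Dixon's test was run on 53 sets of libraries (a measure within a group), and chance flags about 1 in 20 of them.

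Over days 7 to 33, 212 genes were lower in white than in red pulp (median log2 fold change -1.94), and 191 of them were lower on day 0 as well. Differences in scaling, in read number and the genes at 0 in white pulp day 11 replicate 1 are argued against as the whole cause, because 209 genes were called lower after TMM rescaling, 184 with every library thinned to 2534073 reads and 211 with the stretches set aside. RNA of macrophages or monocytes is a candidate source, although the cells were sorted as P14 CD8 T cells: within groups, the 194 genes outside the marker list had a median correlation of 0.452 with the macrophage score (189 above 0), against at most 0.0974 in 1000 random sets. The markers Slc40a1, Vcam1 and Apoe stood at 10793, 8500 and 5953 normalized counts in red pulp on day 0 and 1320.4, 1239 and 658 on day 7 (white pulp 538, 457 and 457 and 49.9, 48.6 and 83.2), and 7 of the 20 markers had a mean of at least 50 in every white pulp group. With the scores as covariates the median became -0.52, its SE rose from 0.40 to 0.73 and 0 genes were called, and a change in the T cells themselves stays open, as untested.

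For 22 named genes limma's F test found that the difference between the compartments changed with the day. The largest log2 term against day 0 (its day, then the adjusted p of the F test) was toward white pulp in Zeb2 (4.21 on day 33, 2.27e-08), Lgals3 (4.24 on day 7, 5.24e-07), Cd68 (3.71 on day 33, 1.15e-06), Itgax (3.80 on day 11, 4.25e-06), Axl (4.14 on day 11, 3.37e-05), Entpd1 (4.98 on day 7, 3.41e-05), Tyrobp (3.27 on day 33, 5.13e-05), Bhlhe40 (1.77 on day 33, 0.00013), Pira2 (4.23 on day 33, 0.000135), Klrk1 (1.49 on day 15, 0.000186), Miat (3.35 on day 11, 0.000336), Lilrb4 (2.76 on day 11, 0.00199), Itga4 (0.74 on day 15, 0.00316), Fcer1g (3.17 on day 33, 0.0055), Adamdec1 (7.75 on day 11, 0.00613), Klre1 (2.36 on day 15, 0.0153), Col14a1 (5.85 on day 11, 0.0267), Hpgds (3.39 on day 11, 0.0277) and Ctsc (0.84 on day 33, 0.0487). It was toward red pulp in Cd8a (-0.43 on day 11, 0.00393), Pdcd1 (-3.50 on day 33, 0.00754) and Atp5a1 (-0.52 on day 11, 0.0209).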

How the results depend on the processing

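Chosen after the data were seen were the tests with the macrophage and B cell scores as covariates and with the missing stretches set aside. All 17 counts of called genes stayed within 1.5 times the reported count under TMM rescaling and with the stretches set aside. Library quality weights gave 616, 256, 72, 368 and 1 genes for white against red pulp on days 0, 7, 11, 15 and 33, 381 for the mean of days, and 3611 (white) and 3606 (red) for day 33 against day 7. Fits to the groups compared alone, with fewer libraries to estimate the spread, gave 383 on day 0, 396 on day 15 and 2346 for day 11 against day 0 in white pulp. With the scores as covariates, white against red pulp gave 58 genes on day 0 and 0 on day 7, 0 on day 11, 0 on day 15 and 0 for the mean of days, and the other moved counts were 2129 (day 15, white), 1971, 969 and 719 (days 7, 11 and 33, red), 488 (day 33 against 7, red) and 55 (interaction). DESeq2 called 75, 64 and 133 genes on days 7, 11 and 15 and 290 for the interaction, and edgeR 7 on day 11 and 101 for the interaction. The replicate block gave 42 genes on day 11, 134 on day 15 and 0 on day 33. Of 22 same-numbered pairs 6, with all 3 on day 33, correlated above 0.1 (all required). But 12, with all 5 on day 15, matched their own number best. The pairs' median was 0.07 (others -0.01). Pairing, left out of the main fits, is favored on some days but open. On day 15 a pseudocount of 5 gave 256 and a minimum mean of 1 gave 146, and on day 33 that minimum gave 2 genes, in place of 0 by limma (262 at an unadjusted p below 0.05) and 0 by edgeR and DESeq2. With each library left out in turn the counts were 23 to 63 genes on day 7, 2 to 13 on day 11, 31 to 83 on day 15, 0 to 1 on day 33, 1093 to 1810 for day 33 against day 7 in red pulp and 129 to 251 for the interaction. Signs turned with the scores as covariates for Il7r in red pulp on day 33 (-0.21), Tcf7 on day 0 (-0.21) and Fcer1g on day 7 (0.43) between the compartments, and Cd300e (0.72), Mertk (0.13), Vcam1 (0.01) and Gzmb (0.05) for the mean of days, and without red pulp day 33 replicate 4 for Il7r in red pulp (-0.07, up to 0.19 without replicate 3). For the other moved values the cause was not tested.

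Of 1128 called results for genes that the naming rule gives, 729 were called in the same direction under every alternative, 949 under every alternative except the covariates, and 22 turned sign under some alternative. For white against red pulp the first number was 5 of 84 on day 0, 0 of 11 on day 7, 0 of 5 on day 11, 0 of 18 on day 15 and 0 of 20 for the mean of days. Of 119 list results in the text, 46 lost their call with an estimated correlation, and with fry 9 lost and 15 gained it. With 1 library left out, camera calls of lists ended in 30 of 1154 fits and 8 were gained, and the uncalled day 0 platelet (adjusted p 0.355 to 0.975) and day 7 white pulp cholesterol lists (0.609 to 0.904) turned direction. Thinning all libraries to 2534073 reads left 1241, 33, 13, 64 and 0 genes between the compartments on days 0, 7, 11, 15 and 33 and 199 for the mean of days.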

Other observations

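Tests chosen after the results were seen were the search for runs of genes at 0, the dilution test on the day 0 libraries alone, the test of memory precursor shares and the day 7 splits by macrophage score. Red pulp day 0 replicate 3 listed 0 for 22 neighboring tested genes on chromosome 18 (37661793 to 37841873) and 8 on chromosome 1 (88055388 to 88218997, GRCm38), which hold the gamma protocadherin and Ugt1a clusters. Runs of at least 8 genes were searched for, a length lowered after a first search.

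The naive and memory precursor list was higher in white pulp over days 7 to 33 (mean log2 difference 0.20, 0.09 to 0.31, 25 genes outside the stretches). Genes at 0 in 1 library are argued against. Camera (n = 19 white, n = 17 red) gave p = 0.00202 with score covariates and p = 3e-09 without that library. RNA of other cells stays open, as the macrophage score differs by compartment (list mean 0.21, with scores 0.24). Dilution of T cell RNA in red pulp cannot be told apart from a change in the T cells: 12 T cell identity genes were higher by 0.092 (0.03 to 0.15), and their upper limit lies below the list mean, which beforehand was to rule dilution out. That rule left out the list's own spread (interval above), and with it the difference from the list, a condition added afterwards, was 0.11 (-0.02 to 0.24), which includes 0. A larger share of memory precursor cells in white pulp may contribute and stays open, since terminal effector genes differed by -0.07 (-0.16 to 0.02, n = 19 and n = 17, limma's camera p = 0.0901). On day 0, dilution may also raise genes in white pulp (445 called, median 0.47, and 18 with the day 0 libraries alone and 55 with quality weights): the 15 identity genes were higher by 0.25, and 1 of them was called. The interval set beforehand leaves this open (-0.21 to 0.70, widened by genes at 0 in white pulp day 11 replicate 1), and the interval from the day 0 libraries alone goes with dilution (0.16 to 0.34).

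Up to 100 splits of the libraries into groups of the same sizes were fitted, the real one included. For white against red pulp on days 0, 11 and 15 and for the mean of days, 1 of 100 splits, the real one, gave as many genes (1414, 17, 87 and 215, highest other 827, 2, 1 and 26), so chance can be excluded. On day 0 each of the 99 other splits called some genes. On day 7 the count alone does not exclude chance, as 2 of 35 splits gave at least 47 (highest other 291, 54 with the replicate block). A test chosen afterwards argues against chance: 1 of 35 splits, the real one, set the macrophage score as far apart (3.24, highest other 2.26). The 46 genes lower on day 7 were all lower on day 0, in other libraries. The split with 291 parted replicates 1 and 4 from replicates 3 and 5 in both compartments and called several times the real count, which points to a structure of the samples. On day 33 all 56 splits gave at least 0 (highest other 87, the other tools also calling 0, and 262 genes at an unadjusted p below 0.05 by limma). Between days, the splits argue against chance for each comparison. In white pulp 1 of 100 splits gave as many for days 7, 11, 15 and 33 against day 0 and day 33 against day 7 (4222, 3995, 3456, 3502 and 2235, highest other 3514, 1660, 1517, 1397 and 1247). In red pulp this was 1 of 100, or 1 of 56 for day 33 against day 0 and 1 of 35 against day 7 (4564, 3446, 2632, 2701 and 1742, highest other 3751, 1260, 893, 1642 and 1219). For the interaction 3 of 100 splits gave at least 165 genes (highest other 588). Splits also remove the compartment difference, so chance stays open. The 588 points to a structure of the samples that was not tested, and the replicate block gave 169 genes.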
